A study of Homo sapiens with 120 samples.

How the data were processed

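RNA was sequenced from LNCaP95 cells, an androgen-independent derivative of the LNCaP prostate cancer line. Per the labels, the cells grew in phenol red-free medium with charcoal-stripped serum, and poly(A) libraries were made with a stranded TruSeq kit and run on an Illumina NextSeq sequencer. The labels put 120 libraries into 40 groups of 3. In the hairpin experiment, 48 libraries in 16 groups hold shARv7 cells and shGFP control cells from 1 batch date, and shARfl cells and their own shGFP cells from another, at ethanol and at 0.1, 1 and 10 nM dihydrotestosterone (DHT) for 24 h. In the siRNA experiment, 72 libraries in 24 groups hold shGFP, shARv7 and shARfl cells transfected for 24 h with siCtrl, siNCOR1, siNCOR2 or siNRIP1, under 2 oligo labels each, so 6 libraries per target and line. Samples were grouped by their treatment and transfection labels, and 0 samples stayed unassigned. Arm, hairpin and batch date go together in the hairpin experiment, and so do the shGFP line and its batch date in the siRNA experiment, so within each experiment these cannot be told apart. The labels do not say that the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

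The 17 files used here are the authors' own comparison tables, 8 for the hairpins and 9 for the siRNAs, with 0 columns of values per sample. Per the labels, the authors used the hg19 build and DESeq, with no version; the aligner and the gene annotation are not given in the sources used here. Per the file headers, each deposited table lists per gene a mean normalised signal, scaled within that table only, a log2 fold change of the knockdown against its control with its standard error on the log2 scale, a test statistic (a score), a p-value and an adjusted p-value. In each deposited table the statistic was the log2 fold change divided by its standard error, to within 1.99e-13. The authors' adjusted p-value was the Benjamini-Hochberg value over the genes that have it, to within 1.77e-13. In 15 of the 17 tables, genes below a level that differed between tables had no adjusted p-value. In the authors' deposited tables the standard error was at most 0.27 for the hairpins and 0.09 for the siRNAs at any level of a gene; fold changes shrunken towards 0 would give this, which was not tested, so sizes are not compared between the experiments. Whether each siRNA table pools both oligo labels is taken from the sample descriptions, which name 1 table for both; no table is named for the siCtrl samples. The direction of the contrasts was checked on the targets of the hairpin and siRNAs, and for shARv7, which has no such target here, on the mean levels of the lines in the siRNA tables. Across 9849 genes the level in the shARv7 line over the shGFP line went with the authors' shARv7 fold changes at Pearson r of 0.421 to 0.552, and with their shARfl fold changes at 0.277 to 0.303; genes are not independent replicates. The level in the shARfl line went with the shARfl fold changes at 0.667 to 0.759 and with the shARv7 fold changes at 0.053 to 0.096. The depth per library is unknown from these tables, so no interval or floor that needs it is given.

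A gene was called where the authors' adjusted p-value was below 0.05. Genes with a mean level of at least 50 in all tables of a family were counted as common where they were called in the same direction in all 4 dose tables or all 3 lines, beside the product expected for independent lists. The AR-V7 and full-length AR effects were compared with limma 3.58.1 in R 4.3.3, on the authors' log2 fold changes, 4 dose tables against 4, with Benjamini-Hochberg adjustment. The change with dose was limma's slope of the log2 fold change on dose rank (0, 1, 2 and 3). These models take the doses as replicates. Overlaps were tested two-sided with Fisher's exact test over genes tested in both tables, and the median change of a set was placed among 10000 random sets matched on level in 20 bins (seed 20161). In all, 21 gene lists were tested with limma's cameraPR on the authors' statistic over genes at a level of at least 50, with a preset correlation of 0.01 and adjustment over the lists of a table. A correlation could be estimated for the hairpin arms alone, over the 4 dose tables with limma's camera, and 0 of the 18 lists that could be tested so passed with it in either arm. That estimate counts joint movement of a list's genes over the doses as correlation, a response to DHT included. It cannot tell a dose response from noise, and the test with it rests on the spread between 4 tables alone, which makes passing harder. For replication-dependent histone genes with shARfl the estimate was −0.137, below the preset, yet camera's p rose from 4.55e-04 to 0.0369. A list that does not pass with it is not decided by it. An adjusted p given below with an estimated correlation comes from this camera test over the doses. It is not the test of a single dose with only the correlation changed. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

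Named genes were chosen by a rule. For each arm they are AR and the 10 genes that rose and the 10 that fell most by median over the doses, among genes called the same way at all 4 doses. For each siRNA they are NCOR1, NCOR2, NRIP1, AR and up to 8 genes each way among those called the same way in all 3 lines. For the difference between the arms they are the 10 largest each way past the threshold, and members of a list are named where the list is described. The designs, lists, this rule and most alternatives were fixed before the data were examined.

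Transcript length, GC content and 3' UTR sequence were taken from GENCODE release 29, another build than the authors', by gene name alone, and no coordinates were used. Of 23362 symbols in the tables, 92.4% were matched. The trend of a table's statistic (limited to 6 either way for the fit) on GC content, transcript length and level was removed by least squares, and p-values were recomputed. Words of 7 bases were searched for in 3' UTRs of at least 50 bases. The mean log2 fold change of genes with a word, freed of 3' UTR length and GC content, ranked the words in a random part of the genes and was tested in the other genes, at other doses or in the other arm. Shares of genes with a word were set beside 10000 draws matched on 3' UTR length in 20 bins and GC content in 5. These shares take in the genes and doses in which the words were found. The hairpin sequences were not used here, so each word is ascribed to a hairpin by the tables alone.

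The methods were tested on simulated data. The limma comparison recovered 86 of 100 genes with a planted difference of 0.5 on the log2 scale and 100 of 100 with 1, with 5 false calls among 10785 genes. The slopes recovered 75 of 100 genes at a planted rise of 1 over the doses and 100 of 100 at 2. Trend removal recovered 198 of 200 planted genes while false calls fell to 16, from 1880 before it. The planted shifts were large and placed without regard to GC content, so smaller effects, or effects that go with GC content, were not covered. The word scan found 10 of 10 planted words, and the list test called 1 list, the shifted one, of 18. Genes were drawn independently for the list test, so false calls among lists of correlated genes were not covered. Common counts of independent simulated tables averaged 13.6, with 13.6 expected.

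Alternatives were a threshold of 0.01, a change of at least 2 times, other level filters, each dose left out in turn, dose as a block, z tests from the authors' standard errors, other correlations and ranks in the list tests, and other AR-V7 sets in the overlaps. Trend removal (in the comparison of the arms and the slopes, from the log2 fold change), leaving out genes with a word, the estimated correlation and the authors' statistic in place of the log2 fold change were added after the data were seen.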

Results

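Gene expression was measured by RNA sequencing in LNCaP95 cells with a hairpin against the AR splice variant AR-V7 (shARv7) or full-length AR (shARfl), and with siRNAs against the corepressors NCOR1, NCOR2 or NRIP1. The data are 120 libraries in 40 groups of 3. The authors' deposited tables of the hairpins list 19241 to 20421 genes, and those of the siRNAs 16530 to 16805, each as a log2 fold change against the control of its own comparison. Fold changes below are those of the authors' deposited tables, in the order ethanol, 0.1, 1 and 10 nM DHT for the hairpins and shGFP, shARv7 and shARfl cells for the siRNAs.

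The AR-V7 comparison asks which genes depend on the variant, which lacks the ligand-binding domain of AR. In the authors' deposited tables RELN, which encodes the secreted glycoprotein reelin, rose by 1.26, 1.82, 1.94 and 1.65 (standard errors 0.15 to 0.16), and SOAT1, which esterifies cholesterol, rose by 1.29, 1.57, 1.53 and 1.36. The vesicle protein gene SYT4 rose by 1.35, 1.42, 1.47 and 1.18 in the authors' deposited tables, and PODXL, which encodes the sialomucin podocalyxin, by 1.32, 1.46, 1.34 and 1.20. The other raised genes named by the rule were TMEM109, DUSP5, TMPPE, POMK, ANO6 and GATSL2, from 0.79 (POMK at ethanol) to 1.54 (POMK at 10 nM) in the authors' deposited tables. Among lowered genes, the authors' deposited tables give AASDHPPT, which activates acyl carrier proteins, at −1.10, −1.30, −0.98 and −1.26 (standard errors 0.10 to 0.12), and the actin-binding tropomyosin gene TPM4 at −1.13, −1.32, −1.05 and −1.06. WARS, a transfer RNA synthetase gene, UBE2V2, NHP2L1, KCNMA1, GALNT1, EBAG9, HMMR and TMTC3 fell too, from −0.66 (EBAG9 at 10 nM) to −1.36 (UBE2V2 at 0.1 nM) in the authors' deposited tables. Of these 10 lowered genes, 9 (NHP2L1 not among them) carry in the 3' UTR a word, GTATCAA or AGTATCA, against 2.29 in matched draws. The word was found in a random part of all genes at ethanol and 0.1 nM, so this count is not an independent test. Such words are named here where they went with lower or higher expression in a measure freed of 3' UTR length and GC content, chosen after the data were seen; for this word the raw medians of held-out genes with and without it, −0.003 and −0.016, do not show it.

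Total AR mRNA, which includes the full-length transcript, was not lowered by shARv7. The authors' deposited tables give it at 0.04, 0.06, 0.23 and 0.30 (standard errors 0.03 to 0.04), with adjusted p = 9.9e-13 at 1 nM and 2.0e-13 at 10 nM; AR-V7 itself has no entry of its own in these tables. Classical androgen-induced genes moved apart. In the authors' deposited tables KLK3, the gene of prostate-specific antigen, fell, to −1.14, −0.81, −0.73 and −0.57, and KLK2 to −0.99, −0.90, −0.56 and −0.22. ACPP, the gene of prostatic acid phosphatase, rose by 1.35, 1.35, 0.95 and 0.59 in the authors' deposited tables. Of 19 measured androgen-induced genes, 5 fell at all 4 doses (KLK3, KLK2, FKBP5, ELL2, STEAP2), ACPP rose and 13 did neither; adjusted over the list alone, 5 fell and 2 rose. FKBP5 and STEAP2, 2 of the 5 that fell, carry the word above, beside 15.0% in matched draws for genes lowered at all 4 doses. The list passed the test at 0 doses, with adjusted p = 0.103 to 0.568, and at 10 nM its median statistic was above 0 while the test pointed down.

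Several genes of cholesterol and fatty acid synthesis rose with shARv7. In the authors' deposited tables HMGCR, the rate-limiting enzyme of cholesterol synthesis, rose by 0.56, 0.78, 0.66 and 0.43 (standard errors 0.04 to 0.05). The low-density lipoprotein receptor gene LDLR rose by 0.50, 0.67, 0.44 and 0.31 in the authors' deposited tables, and INSIG1, which holds back SREBP processing, rose by 1.11, 1.31, 1.22 and 1.08. Of 14 measured members, 8 rose at all 4 doses (HMGCR, LDLR, SQLE, INSIG1, SREBF2, DHCR7, FASN, SCD), LSS fell and 5 did neither. Adjusted over the list alone, 10 rose. The list test was up at all 4 doses, with adjusted p from 4.39e-13 at 0.1 nM to 2.93e-06 at 10 nM. Over the 4 doses together, camera gave adjusted p = 0.00596 at the preset correlation, but adjusted p = 0.533 with an estimated correlation. INSIG1 and SCD, 2 of the 8 raised members, carry a word that went with higher expression in both arms by that measure, CCTGAAA or CCCTGAA, though not by raw medians of held-out genes (−0.009 with and −0.012 without). In matched draws for genes raised with shARv7, 33.8% carry it, so these members show no excess.

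Of the mitosis genes a part rose at all doses. The authors' deposited tables give MKI67, a marker of cycling cells, at 0.50, 0.56, 0.75 and 0.69, the mitotic kinase gene AURKA at 0.64, 0.41, 0.39 and 0.48, and CDK1, the kinase that starts mitosis, at 0.54, 0.30, 0.46 and 0.30. Of 20 measured members, 7 rose at all 4 doses (CDK1, CDC20, BUB1, AURKA, TOP2A, MKI67, CENPF) and 13 did neither, also when adjusted over the list alone. The test was up at ethanol (adjusted p = 2.21e-05), 1 nM (0.00571) and 10 nM (0.00287), not at 0.1 nM (0.374). Over the 4 doses together, camera gave adjusted p = 0.00596 at the preset correlation and adjusted p = 0.533 with an estimated correlation. The lowered named gene HMMR, whose protein binds hyaluronan and the spindle, is not in that list.

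A short list of 4 genes was recalled from memory, unchecked, as genes that this study reports to be repressed by AR-V7. It was up at all 4 doses, with adjusted p from 0.00204 to 0.0427. Over the doses together, camera gave adjusted p = 0.0680 at the preset correlation, already not past the threshold, and adjusted p = 0.533 with an estimated correlation. Once the trend on GC content was removed, the list passed at 0.1 and 1 nM. The authors' deposited tables give B4GALT1, a galactosyltransferase gene, at 0.36, 0.58, 0.40 and 0.37, and SNX14 at 0.46, 0.51, 0.46 and 0.25. SLC30A7, a zinc transporter gene, was at 0.17, 0.21, 0.31 and −0.03 in the authors' deposited tables, and HIF1A at 0.21, −0.02, 0.16 and 0.18. Thus 2 of 4 rose at all doses, also when adjusted over the list alone; a list that comes from the study and is tested in its own tables gives no independent evidence of direction. B4GALT1 carries the word CCTGAAA or CCCTGAA.

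In all, shARv7 raised 1822, 2325, 2438 and 2024 genes and lowered 1151, 1994, 2151 and 1778 by the adjusted p of the authors' deposited tables. The trend on GC content, length and level was then removed. Of called genes with a GC value and a level of at least 50, 83.9, 77.7, 71.7 and 76.3% stayed called. Median GC content of raised and lowered genes was 50.5 and 46.2% at 0.1 nM, but 45.4 and 56.2% at 1 nM. Of 10855 genes at sufficient level, 1012 rose and 452 fell at all 4 doses, against 13.6 and 5.74 expected for independent lists. All 4 doses compare the same lines from 1 batch date, so an excess over independent lists was to be expected. A change of at least 2 times held for 41 to 99 genes per dose. Leaving out ethanol moved the lowered count to 776, and leaving out genes that carry a word of any hairpin moved the counts to 427 and 212.

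**Figure D1:**
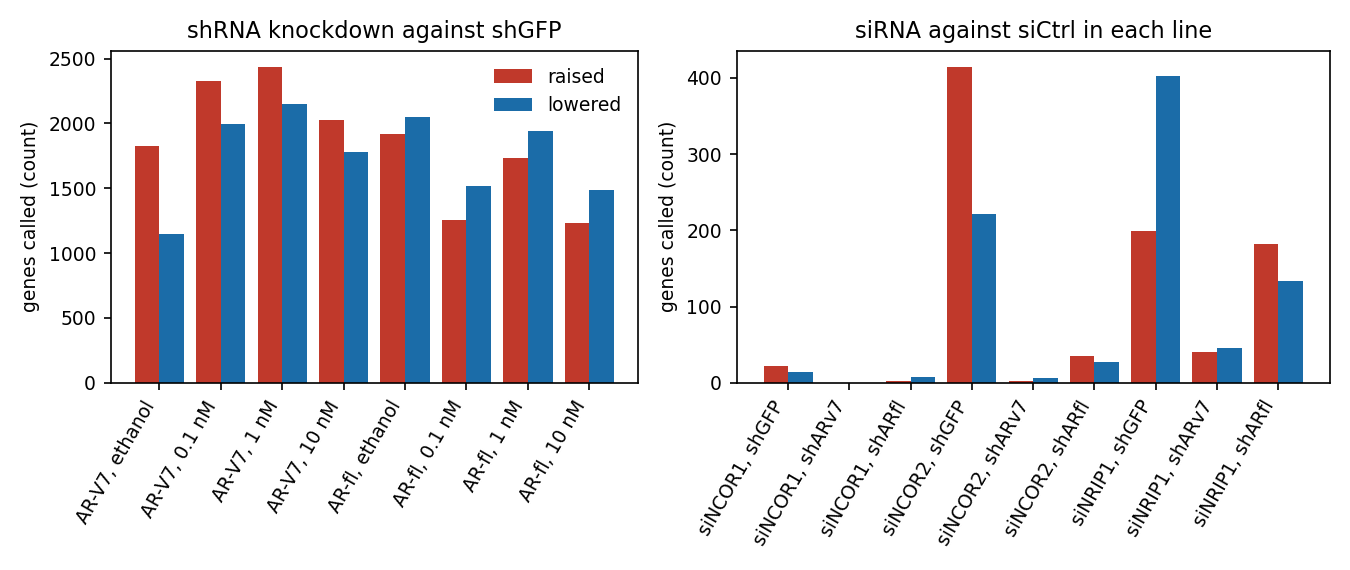
Bars count the genes raised (red) and lowered (blue) at an adjusted p below 0.05 in each of the authors' deposited tables, hairpins on the left (AR-fl is full-length AR) and siRNAs on the right, on separate axes. Each hairpin table holds at least 2720 called genes, and the siRNA tables hold 0 to 637.

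The full-length comparison asks which genes depend on the androgen-bound receptor. In the authors' deposited tables AR fell, to −1.56, −1.45, −1.29 and −1.48 (standard errors 0.05 to 0.15). The growth factor gene IGF1 fell, to −2.07, −2.26, −2.95 and −3.40 in the authors' deposited tables, as did TMEFF2, which encodes a transmembrane protein of prostate and brain, to −2.19, −2.60, −2.48 and −2.58, and the proteoglycan gene SPOCK1, to −1.44, −1.73, −2.51 and −3.22. The other lowered genes named by the rule were COLCA1, ADAM7, SLC45A3, KLK3, ARHGEF26, DUSP27 and TMPRSS2. Among raised genes, the authors' deposited tables give the transcription factor gene ATOH8 at 2.31, 2.39, 2.79 and 3.04 (standard errors 0.15 to 0.21), the myosin gene MYO7A at 1.92, 2.13, 2.17 and 2.72, and SLC5A1, a sodium-glucose cotransporter gene, at 0.32, 1.33, 1.97 and 2.52. PLXDC2, CNIH3, B3GNT6, VAV3, SPRY4, PTBP2 and PRSS1 rose at all 4 doses too, from 0.69 (PRSS1 at ethanol) to 2.33 (PRSS1 and B3GNT6 at 10 nM) in the authors' deposited tables. At adjusted p below 0.01, SLC5A1 passed at 3 doses.

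Androgen-induced genes fell with shARfl, more of them at higher doses. The authors' deposited tables give KLK3 at −1.15, −1.35, −1.86 and −2.19, TMPRSS2, a prostate serine protease gene, at −1.10, −1.23, −1.71 and −2.19, and SLC45A3, which encodes prostein, at −1.32 at 0.1 nM and −3.38 at 10 nM. Of 21 measured members, 9, 10, 17 and 21 fell at the successive doses, and 8 fell at all 4 (KLK3, KLK2, TMPRSS2, PMEPA1, SLC45A3, C1orf116, ELL2, CENPN), the same number when adjusted over the list alone. The list test was down at all 4 doses, with adjusted p from 1.44e-08 at ethanol to 6.65e-65 at 10 nM. Over the doses together, camera gave adjusted p = 5.31e-04 at the preset correlation, but adjusted p = 0.995 with an estimated correlation. The estimated correlation, 0.753, takes in the growth of the loss with dose, so it cannot decide here. C1orf116 carries a word, AAGTCAC or AGTCACA, that went with lower expression across this arm by that measure, as do IGF1 and SPOCK1, 2 of the 9 lowered named genes with a 3' UTR, against 2.17 in matched draws. C1orf116 is 1 of the 8 members that fell at all 4 doses, beside 26.9% in matched draws for genes lowered so.

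Several cholesterol and fatty acid synthesis genes fell with shARfl. In the authors' deposited tables HMGCR was at −0.28, −0.35, −0.42 and −0.94, LDLR at −0.61, −0.71, −0.65 and −1.02, and DHCR7, which makes cholesterol in the last step of its synthesis, at −0.41, −0.38, −0.36 and −0.57. Of 14 members, 7 fell at all 4 doses (HMGCR, LDLR, SREBF2, LSS, DHCR7, SCD, ACACA) and 0 rose, also when adjusted over the list alone. The test was down at all 4 doses, with adjusted p from 3.71e-04 at 0.1 nM to 2.57e-08 at 10 nM. Over the doses together, camera gave adjusted p = 0.00273 at the preset correlation and adjusted p = 0.995 with an estimated correlation. LSS, SCD and ACACA, 3 of the 7 that fell, carry the word AAGTCAC or AGTCACA, beside 26.9% in matched draws for genes lowered at all 4 doses.

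Cell cycle genes moved by dose with shARfl. Mitosis genes were up at ethanol (adjusted p = 3.13e-04) and 1 nM (0.0153) and down at 0.1 nM (0.0473) and 10 nM (0.0200), with adjusted p = 0.995 with an estimated correlation over the doses. DNA replication genes were up at ethanol (adjusted p = 0.00560) and down at 0.1 nM (7.03e-12) and 10 nM (0.0466), with adjusted p = 0.995 with an estimated correlation. At 0.1 nM, 17 of the 20 replication genes fell. The authors' deposited tables give the helicase gene MCM2 at 0.15, −0.65, −0.09 and −0.31, of which the values at 0.1 and 10 nM passed. The order of these changes does not follow the dose. CDKN1A, a cell cycle inhibitor gene among the p53 targets, rose by 0.87, 1.11, 1.30 and 0.60 in the authors' deposited tables, and carries the word CCTGAAA or CCCTGAA. With shARv7, where that word also went with higher expression, CDKN1A fell at all 4 doses.

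In all, shARfl raised 1919, 1259, 1732 and 1235 genes and lowered 2051, 1517, 1938 and 1485 by the adjusted p of the authors' deposited tables. The trend on GC content, length and level was then removed. Of called genes with a GC value and a level of at least 50, 93.2, 94.7, 87.9 and 75.4% stayed called. Of 11967 genes, 484 rose and 673 fell at all 4 doses, against 2.04 and 3.72 expected for independent lists. A change of at least 2 times held for 74 to 309 genes per dose. Leaving out genes that carry a word of any hairpin moved the common counts to 228 and 211.

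The next comparison asks where the effects of the 2 hairpins part. By limma, CDKN1A was lower by −1.39 (standard error 0.12) with AR-V7 knockdown than with full-length AR knockdown, from mean fold changes of −0.42 and 0.97. IGFBP3, which binds insulin-like growth factors, differed by −2.72 (0.41), from −1.05 and 1.67. The integrin gene ITGB1 differed by 1.75 (0.08), from 0.64 and −1.11, and the bicarbonate transporter gene SLC4A4 by 2.36 (0.08), from 1.11 and −1.25. HMGCR differed by 1.10 (0.12) and LDLR by 1.23 (0.10). The cholesterol and fatty acid synthesis list differed between the arms, higher with AR-V7 knockdown, at adjusted p = 5.0e-05 with the preset correlation and adjusted p = 0.837 with an estimated correlation. Androgen-induced genes were also higher with AR-V7 knockdown (adjusted p = 0.00311, and adjusted p = 0.837 with an estimated correlation). Of 10785 genes, limma called 5179 different, 2673 higher and 2506 lower; leaving out genes with a word of either hairpin leaves 3266 of 7262, now with more lower (1760) than higher (1506).

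Genes raised at all 4 doses were shared by the arms. The 112 genes raised in both, against 39.5 expected, included ANO6, MYO7A and PLXDC2 (Fisher's exact test, odds ratio 3.81, adjusted p = 4.89e-25). Another 98 rose with shARv7 and fell with shARfl, against 59.6 expected (odds ratio 1.84, adjusted p = 1.02e-06), SLC4A4 and ITGB1 among them. Genes raised with shARv7 had longer transcripts (median 5298 bases) than those tested (3542), as had genes lowered with shARfl (4515 against 3472.5). The expected number is not matched on length, so whether length accounts for this excess was not tested. The 10 that fell with shARv7 and rose with shARfl, CDKN1A and IGFBP3 among them, did not pass (17.7 expected, adjusted p = 0.0618), and 39 fell in both (26.7 expected, adjusted p = 0.0244). Across genes, the authors' statistics correlated at r of 0.748 to 0.882 between AR-V7 tables, 0.706 to 0.835 between full-length AR tables and −0.152 to 0.136 between the arms; genes are not independent replicates.

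Histone genes and markers of other cell types moved beside these groups. Replication-dependent histone genes, a sign of RNA without poly(A) tails, were down with shARv7 at 1 nM (adjusted p = 0.0236) and 10 nM (6.31e-04). With shARfl they were down at ethanol (0.00560), 0.1 nM (0.0254) and 10 nM (0.0466). Over the doses of each arm, camera gave adjusted p = 0.00596 (shARv7) and 0.00273 (shARfl) at the preset correlation. With an estimated correlation it gave adjusted p = 0.533 and 0.665. The call with shARv7 at 1 nM ended once the trend on GC content was removed. The authors' deposited tables give HIST2H2BE at −0.33, −0.48, −0.56 and −0.56 with shARv7 and at −0.71, −0.71, −0.77 and −0.94 with shARfl. The list of basal and stromal markers was up with shARv7 at all 4 doses (adjusted p = 0.00431 to 0.0110) on 3 members, with its median statistic below 0 and adjusted p = 0.978 with an estimated correlation. The authors' deposited tables give FN1, the fibronectin gene, at 1.08, 1.22, 1.09 and 0.91 and the collagen gene COL1A1 at −0.33, −0.20, −0.55 and −0.32, so the test and the median point opposite ways. The mesenchymal transition list, which holds FN1 too, was up at 0.1 nM (adjusted p = 0.00408) and 1 nM (5.51e-04), again on 3 members with median statistics below 0 (−2.42 and −2.25). Neuroendocrine markers, 3 genes with SYT4 among them, were up at 1 nM with shARv7 (adjusted p = 0.00258, against a median statistic of −0.19) and with shARfl (0.00132). The mesenchymal and neuroendocrine lists were not among those tested with an estimated correlation.

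The dose comparison asks how each effect moves as androgen rises. With full-length AR knockdown the loss of androgen-induced genes grew by dose step for SLC45A3 by −0.84 (standard error 0.07), FKBP5, which encodes a chaperone of steroid receptors, by −0.61 (0.07), KLK2 by −0.44 (0.05), NKX3-1, a prostate homeobox gene, by −0.42 (0.04), TMPRSS2 by −0.38 (0.05) and KLK3 by −0.36 (0.04), by limma's slope at adjusted p of 0.00412 to 0.0176. IGFBP3 rose by 0.87 (0.07) per step. With AR-V7 knockdown the loss of KLK2 shrank by 0.27 (0.05) per step (adjusted p = 6.85e-04) and the gain of ACPP by −0.27 (0.05; adjusted p = 6.63e-04), while IGFBP3 fell by −0.38 (0.05) per step. KLK3 had a slope of 0.18 (0.05) in that arm, which did not pass (adjusted p = 0.0747). The authors' largest standard error differed by dose, at 0.188, 0.215, 0.213 and 0.270 with shARfl and 0.208, 0.242, 0.219 and 0.197 with shARv7. Fold changes shrunken to unlike degrees at different doses would move the slopes, which was not tested. In all, limma called 112 slopes with AR-V7 knockdown (65 rising, 47 falling) and 87 with full-length AR knockdown (41 and 46). Once the trend of the fold changes on GC content, length and level was removed, 58 and 56 slopes were called, among them 56 of the 112 and 55 of the 86 with a GC value; of the genes named here ACPP no longer passed (−0.25, standard error 0.05, adjusted p = 0.0549). A z test of 10 nM against ethanol from the authors' standard errors called 627 (197 rising, 430 falling) and 470 (216 and 254), KLK3 with AR-V7 knockdown among them. With AR-V7 knockdown the more frequent direction thus turned. At a level filter of 200 it turned in both arms (54 rising and 58 falling with AR-V7 knockdown, 48 and 43 with full-length AR knockdown).

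**Figure D2:**
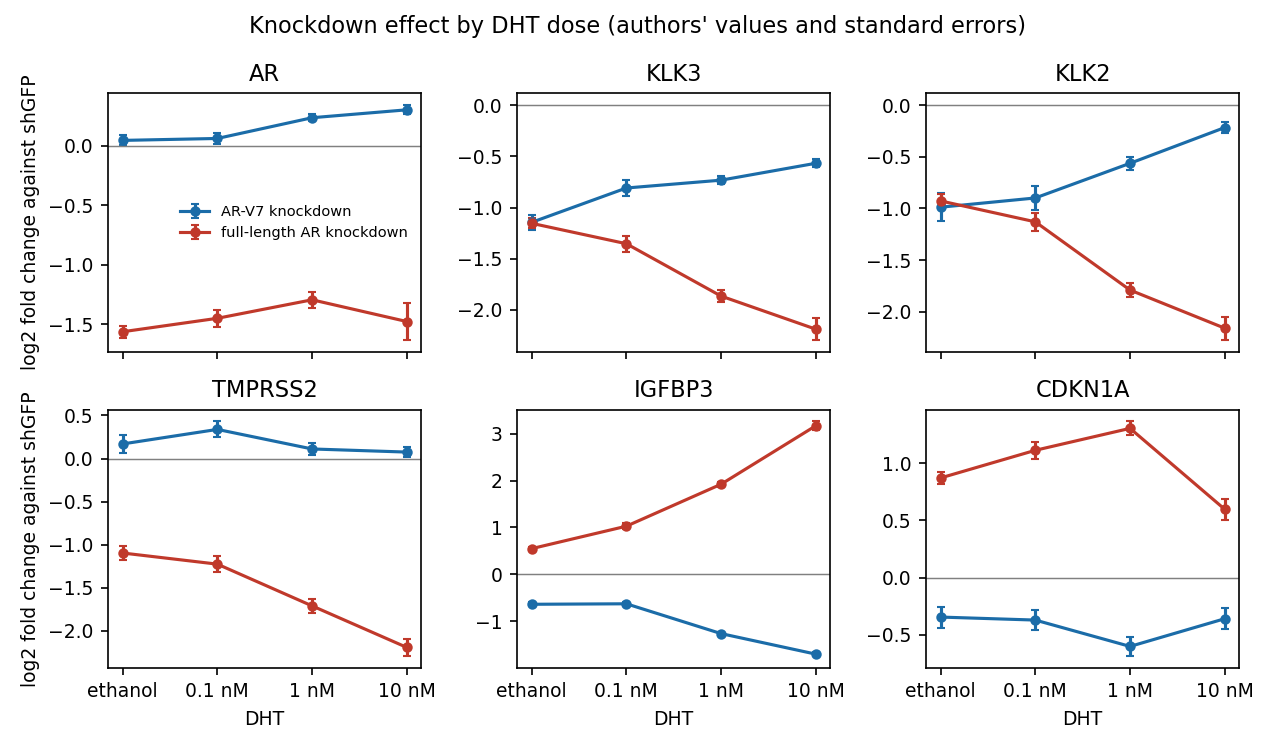
Each panel plots the log2 fold change against shGFP (points) with the standard error (bars) of the authors' deposited tables against DHT dose for AR, KLK3, KLK2, TMPRSS2, IGFBP3 and CDKN1A, with AR-V7 knockdown in blue and full-length AR knockdown in red, each panel on its own scale. KLK3 starts at −1.14 and −1.15 at ethanol and parts to −0.57 and −2.19 at 10 nM.

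The siRNA comparisons ask which genes the corepressors hold in check, in control cells and in cells with the AR-V7 or the full-length AR hairpin. With siNCOR1, the authors' deposited tables give NCOR1 at −0.37 (adjusted p = 2.6e-04), −0.09 (0.26) and −0.18 (1.9e-06), so that its fall did not pass in shARv7 cells. LPCAT3, a phospholipid-remodelling gene and a target of the liver X receptors, rose by 0.16 in shGFP cells (adjusted p = 0.0055), and was at 0.14 and 0.09 in the other lines, in the authors' deposited tables. The list of liver X receptor and SREBP1 genes was up in shARv7 cells (adjusted p = 2.92e-05) and shARfl cells (4.65e-06), and once the trend on GC content was removed also in shGFP cells (0.0249). Adjusted over the list alone, 2, 1 and 4 of its members rose. Also up with siNCOR1 were DNA replication genes in shARv7 (adjusted p = 0.0490) and shARfl cells (1.27e-05), cholesterol and fatty acid synthesis genes in shARv7 (0.0366) and shARfl cells (1.65e-04), and p53 targets in shARv7 cells (0.0490). Replication-dependent histone genes, a sign of RNA without poly(A) tails, were down in shARv7 (0.0186) and shARfl cells (3.91e-06). Once the trend was removed, the calls in shARv7 cells other than the liver X receptor list ended. By the adjusted p of the authors' deposited tables, siNCOR1 changed 36 genes in shGFP cells, 0 in shARv7 cells (332 at an unadjusted p below 0.05) and 10 in shARfl cells, and 0 in common. Of these, 3 of 36 in shGFP and 9 of 10 in shARfl cells stayed called once the trend was removed.

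With siNCOR2, NCOR2 fell, to −0.36, −0.32 and −0.33 in the authors' deposited tables. CAPN5, a calpain protease gene, rose by 0.21, 0.20 and 0.15, the only gene raised in all 3 lines in the authors' deposited tables, though in 0 lines once the trend on GC content was removed. TBL1XR1, which encodes a subunit of the NCOR complexes, was at −0.19, −0.12 and −0.18 in the authors' deposited tables, past the threshold in shGFP and shARfl cells. The list of corepressor complexes, which holds NCOR2 itself, was down in shARv7 (adjusted p = 0.00476) and shARfl cells (5.50e-05). In shARfl cells androgen-induced genes were up (adjusted p = 0.0405), and androgen-repressed genes (0.00425), p53 targets (0.00694), endoplasmic reticulum stress genes (0.00694), liver X receptor genes (0.00694) and the 4 recalled genes (0.00939) were down. Mitosis genes were down in shARv7 (0.0308) and shARfl cells (0.00939), calls that ended once the trend was removed, as did those of the androgen-repressed, stress and recalled genes. KLK3 rose by 0.18 in shARv7 cells in the authors' deposited tables, which was no longer called once the trend was removed. In all, siNCOR2 changed 637, 9 and 63 genes by the adjusted p of the authors' deposited tables. Of those with a GC value and a mean level of at least 50, 2 of 631, 1 of 3 and 13 of 62 stayed called once the trend was removed.

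With siNRIP1, NRIP1 fell, to −0.91, −0.50 and −1.14 in the authors' deposited tables. HMGCS2, the rate-limiting enzyme of ketone body synthesis, rose by 0.29, 0.25 and 0.21, EFCAB4A by 0.19, 0.19 and 0.26, and RILP, a lysosome-trafficking gene, by 0.17, 0.20 and 0.29 in the authors' deposited tables. VMA21, an assembly factor of the vacuolar proton pump, fell, to −0.26, −0.20 and −0.25, and so did CADPS2, a vesicle-release gene, to −0.21, −0.17 and −0.20 in the authors' deposited tables. Of these, HMGCS2 stayed called in all 3 lines once the trend on GC content was removed. Genes of endoplasmic reticulum stress and the amino acid response were up in shGFP (adjusted p = 0.0107), shARv7 (9.02e-11) and shARfl cells (1.20e-04), and of 12 members 3, 4 and 2 rose, or 5, 8 and 5 adjusted over the list alone. The authors' deposited tables give TRIB3, a pseudokinase gene of this response, at 0.21, 0.18 and 0.16 and CHAC1, which degrades glutathione, at 0.19, 0.21 and 0.20, each past the threshold in shGFP and shARv7 cells. DNA replication genes were down in shARv7 (0.0316) and shARfl cells (1.04e-06), mitosis genes in shARv7 cells (0.0109), corepressor complexes (2.18e-05) and cholesterol and fatty acid synthesis genes (0.0219) in shARfl cells, and p53 targets were up in shARv7 cells (4.64e-04); of these, the cholesterol call ended once the trend was removed. In all, siNRIP1 changed 601, 87 and 316 genes by the adjusted p of the authors' deposited tables. Across genes, 3' UTRs with the word GGCAGTT had the lowest score in each line (z of −9.07, −12.9 and −8.13). Whether pairing of the siRNA with other transcripts lowered genes here was not tested. Of the called genes with a GC value and a mean level of at least 50, 9 of 598, 19 of 87 and 111 of 304 stayed called once the trend was removed.

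AR was not called with any of the 3 siRNAs in any of the 3 lines, at −0.02 to 0.08 in the authors' deposited tables. Without values per library no correlation could be estimated for the siRNA lists, and 14 of the 28 calls held at a preset 0.1. Whether an effect differs between the lines was not tested, and the shGFP line comes from another batch date than the other 2.

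**Figure D3:**
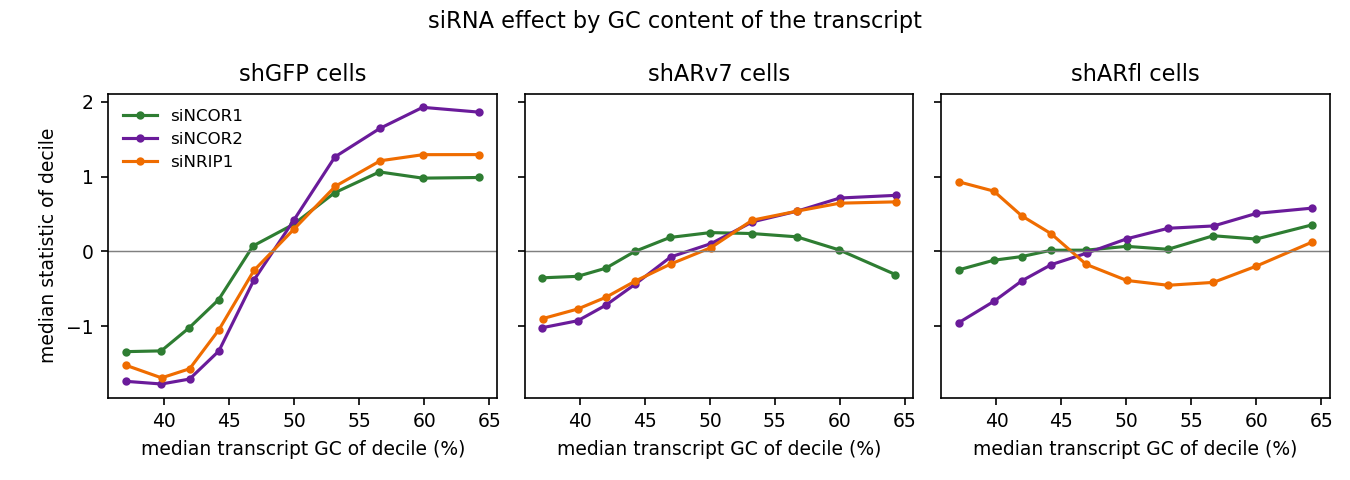
Lines join the median statistic of the authors' deposited tables (vertical axis) over deciles of genes by transcript GC content in percent (horizontal axis), per siRNA and line. In shGFP cells all 3 siRNAs rise with GC content, at rank correlations of 0.539 (siNCOR1), 0.773 (siNCOR2) and 0.714 (siNRIP1) across genes, while siNRIP1 in shARfl cells goes the other way at −0.274.

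The overlap asks whether genes that rise on AR-V7 knockdown also rise when a corepressor is lost in control cells. DHCR7, DHCR24 and ERBB2 were among 77 genes raised by both shARv7 and siNCOR2, against 40.8 expected (Fisher's exact test, odds ratio 2.19, adjusted p = 7.88e-08). SREBF2, DHCR7, DHCR24 and B4GALT1 were among 41 raised by both shARv7 and siNRIP1, against 19.3 expected (odds ratio 2.48, adjusted p = 3.95e-06). LPCAT3 alone was raised by both shARv7 and siNCOR1, against 2.47 expected (odds ratio 0.376, adjusted p = 0.503). DHCR24 and ERBB2 were named after their values were seen. The median of the AR-V7 raised set lay at percentile 20.95 of random sets with siNCOR2 (0.02 to 84.9 under the alternatives), 90.89 with siNRIP1 (2.07 to 99.15) and 0 with siNCOR1. At an siRNA adjusted p below 0.01 the odds ratio was 2.72 with siNCOR2 (adjusted p = 0.398) and 0.913 with siNRIP1 (adjusted p = 1). Once the trend on GC content was removed, 2, 0 and 1 of the genes tested in both were called raised with siNCOR1, siNCOR2 and siNRIP1, and 0 of these were in the AR-V7 set.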

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

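The comparison of the arms and the test of other splits were chosen before the result was seen, and leaving out genes with a hairpin word, trend removal and the authors' statistic were chosen after.

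ID1, SMAD6 and SMAD9 were lower with AR-V7 knockdown than with full-length AR knockdown by −1.70 (standard error 0.21), −1.39 (0.16) and −1.39 (0.09) on the log2 scale by limma, from mean fold changes of −0.44 and 1.26, −0.17 and 1.22, and −0.43 and 0.96. The other named genes lower with AR-V7 knockdown were IGFBP3 by −2.72 (0.41), PTBP2, which encodes a splicing regulator, by −2.01 (0.09), FAXDC2 by −1.65 (0.20), SAMD11 by −1.50 (0.13), DUSP2 by −1.48 (0.16), SELENBP1 by −1.47 (0.16) and CDKN1A by −1.39 (0.12). Higher with AR-V7 knockdown were TMEFF2 by 2.52 (0.09), SLC4A4 by 2.36 (0.08), the purine receptor gene P2RY1 by 2.10 (0.17), the phospholipid synthesis gene CDS2 by 1.88 (0.07) and SLC45A3 by 1.87 (0.37). ARHGEF26 differed by 1.79 (0.07), ABHD2 by 1.78 (0.14), ITGB1 by 1.75 (0.08), TMPPE by 1.75 (0.11) and TMPRSS2 by 1.73 (0.18). All were singled out by the test of the difference between the arms, in which their adjusted p was at most 8.9e-04 (SLC45A3). In the 211 comparisons that 11 alternatives allow, these 20 genes kept their sign and stayed past the threshold, with a highest adjusted p of 0.0125. The others give no value: CDS2, ABHD2, ITGB1, PTBP2, FAXDC2 and SMAD6 are among the genes left out for a hairpin word or for lack of a 3' UTR, so they have no value under that alternative, and P2RY1, TMPPE and FAXDC2 are under the level filter of 200.

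By the same test 5179 of 10785 genes differed, 2673 higher and 2506 lower with AR-V7 knockdown, which singles out the arms as a whole. Of the 35 splits of the 8 tables into 4 and 4, 1, the real one, gave as many genes, and the highest of the others was 0. Every other split puts the difference between the arms into the spread within its groups, so few calls were to be expected there. The doses of an arm are also not independent replicates, so the splits cannot exclude chance. The split shows that the tables of an arm resemble one another, not why. Arm, hairpin and batch date go together in the hairpin experiment, so the split cannot tell effects of AR form, hairpin and batch apart. In the siRNA experiment shARv7 and shARfl cells share a batch date. There, across 9849 genes, the shARfl level over shGFP went with the shARfl fold changes at Pearson r of 0.667 to 0.759. With the shARv7 fold changes r was 0.053 to 0.096. For the shARv7 level these were 0.277 to 0.303 and 0.421 to 0.552. Across these genes this argues against batch date as the whole cause. AR form and hairpin still cannot be told apart. Without genes that carry a word of either hairpin or have no 3' UTR, 3266 of 7262 genes differed, 1506 higher and 1760 lower, so that the more frequent direction turned.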

How the results depend on the processing

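Trend removal, leaving out genes with a word, the estimated correlation and the authors' statistic were alternatives chosen after the data were seen. Of 173 values of the comparisons under alternatives, 99 kept their direction and side of the threshold (counts within 1.5 times), 67 moved and 7 reversed. Of 287 values of named genes, 275 stayed past the threshold with the same sign, 12 no longer passed (of SLC5A1, CAPN5, HMGCS2, RILP, EFCAB4A, VMA21 and CADPS2) and 0 reversed.

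With a change of at least 2 times, 47, 99, 76 and 41 genes were left with AR-V7 knockdown by dose and 74, 128, 176 and 309 with full-length AR knockdown. For siNCOR1 that left 0 in shGFP and 0 in shARfl cells, for siNCOR2 0, 0 and 0 in the 3 lines, and for siNRIP1 0, 0 and 1. A stricter call lowers a count by construction. At an adjusted p below 0.01, full-length AR knockdown changed 1820 genes at 0.1 nM and 1697 at 10 nM, siNCOR1 6 in shGFP and 5 in shARfl cells, siNCOR2 20, 5 and 28, and siNRIP1 47, 37 and 81. The genes lowered at all 4 doses with AR-V7 knockdown became 301. Adjustment over genes at a level of 10 or more gave 342 and 2 for siNCOR2 in shGFP and shARv7 cells. Removal of the trend on GC content, length and level left 7 genes for siNCOR1 in shGFP cells, 4, 1 and 17 for siNCOR2 and 10, 19 and 144 for siNRIP1.

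Called at 3 or more doses, a looser rule, were 1567 raised and 1031 lowered genes with AR-V7 knockdown and 888 and 1133 with full-length AR knockdown. Leaving out each dose in turn gave 1051 to 1240 raised and 503 to 776 lowered genes with AR-V7 knockdown (776 without ethanol), 520 to 716 and 710 to 911 with full-length AR knockdown, and 4073 to 4476 for the difference between the arms. Without genes that carry a word or have no 3' UTR, which tests fewer genes, the counts were 427 and 212 with AR-V7 knockdown, 228 and 211 with full-length AR knockdown, and 3266 for the difference. In 2 or more lines, a looser rule, siNCOR1 lowered 2 genes, siNCOR2 raised 12 and lowered 4, and siNRIP1 raised 25 and lowered 29.

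The difference between the arms stayed within 1.5 times of 5179 with dose as a block (5428), level filters of 10 (5857) and 200 (3668), a z test (6465), the authors' statistic (4992) and the trend on GC content, length and level removed (5259). Slopes with dose became 627 (AR-V7) and 470 (full-length AR) by the z test of 10 nM against ethanol, which rests on the authors' standard errors instead of the spread between doses, and 58 and 56 with the trend removed; the cause was not tested.

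List calls fell from 20 to 12 in the full-length AR tables at preset correlations of 0.05 (12) and 0.1 (12), and from 28 to 18 (0.05), 14 (0.1) and 16 (ranks) in the siRNA tables. Over the 4 dose tables of an arm, 3 lists passed at the preset correlation, and 0 and 0 with an estimated one. A higher preset correlation widens the test by construction. The estimated one takes in joint movement with dose, and the test with it also rests on the spread between 4 tables alone. The loss of calls with it is thus not set by correlation alone.

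At an siRNA adjusted p below 0.01, the overlap with AR-V7 raised genes had an odds ratio of 2.72 for siNCOR2, no longer past the threshold, and of 0.913 for siNRIP1, a reversal; the cause was not tested. The percentile of the siNCOR2 median, 20.95, became 0.14 and 0.02 with the AR-V7 set called at 3 or more and 2 or more doses, 84.9 with the trend removed and 54.84 without genes with a control hairpin word, the last 2 reversals. The percentile of the siNRIP1 median, 90.89, became 26.84 and 2.07 (reversals) with those sets, 99.15 with the trend removed and 98.53 without those genes; the cause was not tested. Neither median kept its direction under all of these settings, whereas that of siNCOR1 stayed at percentile 0 under each of these settings, below the random sets. For siNCOR1 the odds ratio, 0.376, reversed to 3.96 at 0.01 (3 raised genes, adjusted p = 0.450). With the trend removed it was 0 for siNCOR1 (2 raised genes) and 0 for siNRIP1 (1 raised gene), the latter a reversal with 0.0879 shared genes expected, and none could be given for siNCOR2 with 0 raised genes.

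No paired analysis was possible because no values per sample were used here, only tables of comparisons. For the same reason the other models on counts, leaving out each replicate and the replicate block were planned and not run. The depth per library is unknown, so what it limits cannot be given.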

Other observations

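The tests of words in 3' UTRs and of shared siCtrl libraries were chosen only after the results were seen; those of GC content and of the same corepressor were chosen before.

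Some gene lists moved at single doses. Androgen-repressed genes were up with shARv7 at ethanol (adjusted p = 0.00430) and 0.1 nM (0.0305), and GRB10, an adaptor of insulin receptor signalling, stood at 0.37, 0.33, 0.34 and 0.32 in the authors' deposited tables. Liver X receptor and SREBP1 genes were up at 0.1 nM (adjusted p = 0.00583), where the authors' deposited table gives SREBF1 at 0.55 and LPCAT3 at 0.63. Endoplasmic reticulum stress genes were down with shARv7 at 10 nM (adjusted p = 0.00634), where the authors' deposited table gives ASNS at −0.27, CHAC1 at −0.34 and XBP1, which went the other way, at 0.18. Hypoxia and glycolysis genes were up with shARfl at 10 nM (adjusted p = 0.0267), where the authors' deposited table gives PDK1 at 0.67. XBP1 and PDK1 carry the word CCTGAAA or CCCTGAA. With an estimated correlation over the doses these lists had adjusted p = 0.533 (androgen-repressed and liver X receptor), 0.560 (stress) and 0.995 (hypoxia).

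Other lists were called in no hairpin table or in no table. The p53 targets had adjusted p = 0.0898 to 0.387 with shARv7 and 0.441 to 0.912 with shARfl, though CDKN1A moved in both, and corepressor complexes had 0.341 to 0.914 and 0.172 to 0.876. Of the 21 lists, 6 were called in 0 tables, with lowest adjusted p of 0.137 (circadian REV-ERB targets), 0.151 (glucocorticoid receptor), 0.0581 (immediate early), 0.0881 (interferon), 0.0675 (luminal lineage) and 0.810 (retinoic acid receptor, tested in 4 tables). NR3C1, the glucocorticoid receptor gene, stood at 0.78, 0.49, 0.55 and 0.52 with shARv7 in the authors' deposited tables, and carries the word CCTGAAA or CCCTGAA.

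Genes lowered by each hairpin were rich in a 7-base word of the 3' UTR, in a measure freed of 3' UTR length and GC content that was chosen after raw medians of held-out genes with and without the word were seen not to part for AR-V7 (−0.003 and −0.016). Among genes lowered at all 4 doses, 30.3% carry GTATCAA or AGTATCA with AR-V7 knockdown (15.0% in matched draws) and 49.3% carry AAGTCAC or AGTCACA with full-length AR knockdown (26.9%), each at permutation p = 0.0001, the smallest the draws can give. These shares take in the genes and doses in which the words were found, so that p is partly set by the choice of word. Only the held-out genes test the words. A candidate explanation for this excess is pairing of each hairpin's seed with other transcripts: in held-out genes at other doses these words ranked 1 and 2 of 16384, and the word of the other hairpin was not in excess (20.1% against 19.0%, and 20.4% against 20.6%). Pairing of the 6-base core in the 3' UTR is argued against as the whole cause. The core accounts for 25.4% (21.7 to 29.0) and 34.9% (30.9 to 38.6) of the lowered genes beyond draws, under a bound of 50% set after the data were seen. Other sites and indirect effects of a hairpin were not covered, so the test cannot exclude that the hairpin itself moved all of these genes. Loss of AR-V7 or of full-length AR stays open for the rest, untested, and the hairpin sequences were not used here.

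Of 110 genes with a 3' UTR that rose at all 4 doses in both arms, 52.7% carry CCTGAAA or CCCTGAA, against 30.6% in matched draws (permutation p = 0.0001, the smallest the draws can give). Since these 110 genes were not confined to the held-out ones, that p is partly set by the choice of word. A candidate explanation for part of them is pairing of the shGFP control hairpin's seed, which would lower its targets in the control cells of both arms: in held-out genes the words ranked 16 and 3 of 16384, at permutation p = 0.0002. The raw medians of held-out genes with and without the word lie close (−0.009 and −0.012), so this too rests on the freed measure, and in the full-length AR tables another word, TGAAGTA, scored higher than CCTGAAA (z of 6.16 to 8.87 against 5.00 to 7.37) and was not tested further. A dependence on AR that both hairpins share stays open, untested.

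The siRNA effects in shGFP cells went with GC content, transcript length and level: once that trend was removed, 8.33% of the called genes with a GC value and a mean level of at least 50 stayed called with siNCOR1, 0.317% with siNCOR2 and 1.51% with siNRIP1, though removal also takes out any biology that goes with GC content. Across genes, siNCOR2 in shGFP and siNRIP1 in shARv7 cells, which share no library, correlate at r of 0.539, a direction common to the 2 lines. Chance values of shared siCtrl libraries could give a common direction only within a line, so this correlation does not test them. A candidate explanation is GC bias, as that correlation fell to 0.237 after removal, a ratio of 0.440. Loss of the same corepressor stays open for part. After removal the same siRNA correlated between these lines at 0.363 (siNCOR2) and 0.432 (siNRIP1), more than different siRNAs did (0.237 and 0.228). Between shGFP and shARfl cells the same siRNA correlated at 0.149 (siNCOR2) and −0.068 (siNRIP1). For siNCOR1 in shGFP and shARv7 cells it was 0.262, against 0.154 to 0.205 with different siRNAs, though the fall of NCOR1 did not pass in shARv7 cells. Pairing of the same siRNA with other transcripts was not tested and cannot be told apart from loss of its target here. Genes are not independent replicates.

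The authors' deposited table of siNCOR2 in shARv7 cells calls KRT5 at −0.11, KRT12 at −0.09, KRT13 at −0.06, KRT15 at −0.10, S100A6 at −0.07 and ALDH3A1 at −0.11, genes with a mean level of 2.8 to 9.0 there, named after their values were seen. With siNRIP1, the word with the lowest score was GGCAGTT in all 3 lines (z of −9.07, −12.9 and −8.13), and with siNCOR1 and siNCOR2 it was another word in each line. Pairing of the siRNA's seed with other transcripts was not tested.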
